A study of Mus musculus with 2 samples.

How the data were processed

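Each group was 1 library of dorsal root ganglion cells from mice given tamoxifen and imiquimod, the control from Foxp3 CreER; Penk fl/WT and the Treg_Penk_KO group from Foxp3 CreER; Penk fl/fl animals. Per the labels' protocols, the cervical spine was fixed in 4% paraformaldehyde overnight, ganglia of several cervical levels were taken from both sides, and the pooled tissue was dissociated with collagenase and a Dounce homogenizer. Cells were then profiled with the Chromium fixed RNA kit for multiplexed samples, in which pairs of probes, not reverse transcription, read each gene and a probe barcode marks the sample. The series text calls the assay single-nucleus sequencing whereas the sample labels call it single-cell sequencing of fixed samples. How many mice entered a pool, their sex and the processing date are not given in the sources used here.

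The deposited values are raw UMI counts per gene and barcode, not normalized, made by the authors with Cell Ranger against GRCm39, per the labels' protocols and the file headers. The protocol names Cell Ranger version 7.0 and the header of each count matrix version 8.0.1. Seurat is also named in the submitters' processing notes with no role. The barcodes had already been called as cells, with the smallest barcode at 497 UMIs in the Treg_Penk_KO library and slightly fewer in the control. Both matrices listed the same 19059 genes, of which 2089 had no UMI in the control library and 2409 none in the other. All barcodes of a library carried 1 probe barcode, and 4723 droplet barcodes were found in both libraries. Whether both were loaded into the same channel is not given in the sources used here.

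Barcodes with at least 500 UMIs and 300 genes were kept, which removed 20 control and 14 Treg_Penk_KO barcodes. Both libraries were clustered together without integration in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9). Counts were scaled to 10000 per cell and log transformed, and 3000 variable genes, standardised, gave 40 principal components in double precision. A graph of 15 neighbours was partitioned with Leiden at resolution 1.0. Neurons were clustered again on their own in the same way.

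Clusters were named by resemblance to fixed marker genes of 38 cell types, so each name means that the cells carry those markers and no more. The score of a type was the mean log2 fold of its markers over the median of the other clusters, with 5 CPM added. Generic neuron, cycling, erythroid and central neuron markers took no part in the scores, and clusters named for any sensory neuron subtype were taken as neurons. Among all cells, a neuron subtype needed no lead over other neuron subtypes. A name needed at least 50 cells, a score of at least 1.0, a lead of 0.35 over the next type or at least 2 more of its own markers than of any other type among the top 10 genes (ranked with 20 CPM added), and 3 markers at least 2-fold up. Clusters led by globin genes, holding more markers of another type among their top genes, or shallow with no marker there stayed unnamed. The score and lead limits were set after the clusters had been seen. They left unnamed 2.85%, 5.40%, 3.75% and 0.0064% of control cells and 2.65%, 5.11%, 4.42% and 0.183% of Treg_Penk_KO cells in 4 clusters, and among neurons a cluster of 5.57% and 5.62% and 4 small ones. Classes with at least 100 cells in each library were compared, which left out the meningeal-like cells (48 and 41 cells).

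Removal of doublets called by Scrublet had been planned, but the caller did not work at its automatic threshold. It marked 0 of 15690 control cells and 5386 (44.7%) of the Treg_Penk_KO cells. All cells were therefore kept, a departure made after seeing that outcome. From the share of the other library's droplets that also held a cell of a library (39.1% for the control and 30.1%), multiplets within a library were estimated at 22.8% and 16.8% of cells, taking both libraries to have shared droplets. The matching alternative removed the 3474 and 1790 cells with scores strictly above the cut that these estimates set. Cells tied at the cut were kept, so fewer were removed than estimated.

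UMIs were summed per library and class and divided by the class total to give CPM. Each CPM has an exact Poisson 95% interval, each ratio of Treg_Penk_KO to control an exact conditional binomial interval and each share of cells a Clopper-Pearson interval. Where a library had 0 UMIs the ratio was computed at a floor of 3 counts over the class, without the counting error of the other library. Such intervals are narrow for neurons, which hold most UMIs, and wide in the mural-like cells, and they leave out the spread between animals and between library preparations. The intervals of CPM and of ratios also leave out the spread between cells, because each UMI was taken as independent. With 1 library per group no test between genotypes, p-value or count of changed genes was made.

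Log2 ratios had 1 UMI added to each sum. For each of 31 gene lists, the median log2 ratio over members with at least 20 UMIs was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries, and a list was called outside where it fell beyond the 2.5 or 97.5 percentile. Members were counted as higher or lower from a ratio of 25% above 1 or its inverse. The rule for named genes took those with at least 100 UMIs and 20 CPM in a library and at least 0.25 of their mean level in the class where they were highest, apart from sex-linked, red blood cell and mitochondrially encoded genes. It named the 10 highest and 10 lowest ratios in neurons, 6 each way in satellite glia-like cells and 3 each way in other classes and subtypes. It also named up to 4 members with the most UMIs and 4 with the largest ratio from each list outside the random range, and Penk, Foxp3, the opioid receptors and peptides, Calca, Tac1, Trpv1, Trpa1, Fos, Jun, Egr1, Atf3 and 6 sex-linked genes whatever their values. The text prints a selection of these, and the values of some genes are not reported here. The groups, markers, gene lists, this rule, the comparisons and the first set of alternatives were fixed before the data were examined.

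The computation was tested on simulated data, with counts drawn for 19059 genes at the means and depths of the neurons and 200 genes changed. These were drawn as class sums with no spread between cells, so the coverage below leaves that spread out. The interval of the ratio held the true value for 92%, 92%, 96% and 94% of 50 genes at each of the 4 planted folds, smallest first. It held the true value for 95.4% of 7337 unchanged genes, of which 0 passed the size step. For 37.6% of these unchanged genes the interval left out 1, as their true ratio after scaling to the total was not 1. An interval that leaves out 1 is therefore not by itself a sign of a change in that gene. The direction was right for all planted genes. Of 200 unchanged lists of 25 genes, 7% fell outside the random range. Their members were picked at random and drawn independently. This share therefore does not carry over to the fixed lists, whose genes can vary together.

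Alternatives changed 1 choice at a time. They were no cell filter, at least 1500 UMIs per cell, Leiden resolution 0.5 and 2.0, scaling by the median ratio of genes with at least 50 UMIs, the mean over cells of each cell's CPM, cells thinned to 500 UMIs, neuron subtypes weighted equally, list members with at least 1 or 200 UMIs, and a denominator without unnamed clusters. Chosen after the data were seen were removal of the top-scoring doublets, droplets with a cell of 1 library only, and neurons of named subtypes only. Gene positions came from GENCODE M39 on GRCm39, which placed 19043 genes and left 16 without a position. Plots were drawn with matplotlib 3.10.9.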

Results

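Dorsal root ganglia, the sensory ganglia beside the spinal cord, were profiled as fixed single cells from tamoxifen-treated mice after 3 days of imiquimod, a skin irritant that starts a psoriasis-like inflammation. The control library came from Foxp3 CreER; Penk fl/WT mice and the other library, called Treg_Penk_KO here, from Foxp3 CreER; Penk fl/fl mice, in which the recombinase is driven by the gene of the regulatory T cell factor Foxp3. Each group is 1 pooled library and the number of mice in a pool is not given in the sources used here, so there is no replicate check and no test between the genotypes. The intervals are exact 95% intervals and cover counting error only. The control library held 15710 barcodes with 259136217 unique molecular identifiers (UMIs), a median of 2481 UMIs and 1667 genes per barcode. The Treg_Penk_KO library held 12067 barcodes with 156441497 UMIs, a median of 2243 UMIs and 1551 genes. After filtering, 15690 and 12053 cells were kept.

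Penk, the gene of the enkephalin precursor (ENSMUSG00000045573, GRCm39 chromosome 4, 4132722 to 4141856, minus strand), is the targeted gene and was nearly absent from the Treg_Penk_KO library in neurons and glia alike. Over all cells it had 582 UMIs in the control library, or 2.25 CPM (UMIs scaled to the library or class total, interval 2.07 to 2.44), and 4 UMIs in the Treg_Penk_KO library, or 0.0256 CPM (0.00697 to 0.0655), a level 87.8-fold lower (34.1 to 323). In the control library most of the neuronal signal was in Trpm8 cold-like neurons, cells that carry the menthol and cold channel Trpm8, with 241 UMIs and 79.0 CPM (69.3 to 89.6). There Penk had 0 UMIs in 184 Treg_Penk_KO cells, at least 51.9-fold lower with a floor of 3 counts. Myelinating Schwann-like cells held 155 UMIs (7.65 CPM) against 0, at least 28.8-fold lower, and satellite glia-like cells 37 UMIs (2.76 CPM) against 0, at least 7.19-fold lower.

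The other classes pointed the same way where they had Penk counts to compare. Neurons as a whole had 342 UMIs against 1, 205-fold lower (36.5 to 8110), and neurons other than the Trpm8 cold-like were at 0.475 and 0.00786 CPM, with 1 UMI in the Treg_Penk_KO library, 60.4-fold lower (10.6 to 2409). C-LTMR-like neurons, low-threshold touch neurons with unmyelinated fibres, had 25 UMIs against 1, 18.0-fold lower (2.95 to 741). Mrgprd nonpeptidergic-like neurons had 26 against 0 (at least 5.67-fold lower), proprioceptor-like neurons 19 against 0 (at least 3.27-fold), endothelial-like cells 17 against 0 (at least 5.15-fold) and fibroblast-like cells 12 against 0 (at least 3.13-fold). Macrophage-like cells were the exception, with 2 UMIs in each library. Folds given as at least leave out the counting error of the control. The exact intervals began lower, at 3.75-fold for endothelial-like and 2.17-fold for fibroblast-like cells.

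Penk UMIs were found in 20.9% of 220 Trpm8 cold-like cells of the control library (15.7 to 26.9) and in 0 of 184 in the other, which at 3 counts allows up to 1.63% of cells with a UMI and sets no limit on cells that express the gene. No type was fixed in advance as one that lacks Penk. In the control library the share was 1.03% (0.798 to 1.31) in neurons other than the Trpm8 cold-like, at a median of 11477.5 UMIs against 7242.5 in the Trpm8 cold-like cells, 1.97% (1.48 to 2.58) in myelinating Schwann-like cells at 1865 UMIs and 0.274% (0.0332 to 0.986) in macrophage-like cells at 965.5 UMIs. Over all cells the share was 1.42% (223 cells) against 0.0249% (3 cells). With each cell thinned to 500 UMIs, which left out 0 cells, the share was 0.236% against 0 of 12053 cells (up to 0.0249%), and the summed level was at least 10.2-fold lower.

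Foxp3 had 10 UMIs in 9 control cells and 5 UMIs in 5 Treg_Penk_KO cells. Of these, 5 and 3 UMIs lay in neurons, and the cells had median depths of 66860 and 81756 UMIs against 2489 and 2252 in all cells. In the libraries 6 and 2 cells had UMIs of at least 2 of the Cd3 genes, which encode parts of the T cell receptor complex. None of these held a Penk UMI, and no cluster was named as T cells. The positions of the Penk probes relative to the floxed part are not given in the sources used here, and a probe outside the deleted part checks nothing.

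**Figure D1:**
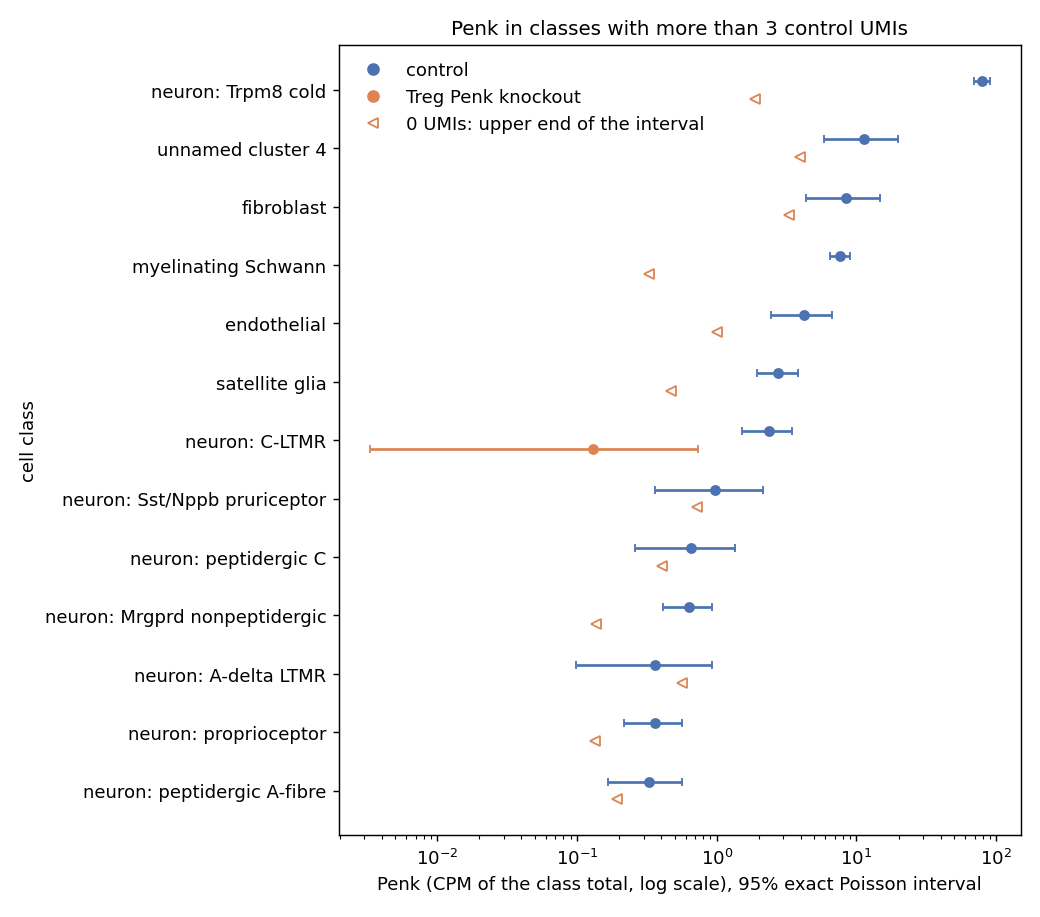
Penk in CPM on a log axis, for each cell class or neuron subtype with more than 3 Penk UMIs in the control library, with exact Poisson 95% intervals; open triangles stand for 0 UMIs and are drawn at the upper end of the interval. Trpm8 cold-like neurons were at 79.0 CPM in the control library and at 0 UMIs in the Treg_Penk_KO library.

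Over all neurons or all cells, the opioid receptors and the other opioid peptide genes were far closer between the libraries than Penk. In neurons, Oprm1, the mu receptor, was at 195 CPM in the control and 225 CPM in the Treg_Penk_KO library (ratio 1.153, 1.14 to 1.17), with a UMI in 56.7% and 54.2% of neurons. Oprm1 was at 707 and 719 CPM in peptidergic C-like neurons, its highest subtype (ratio 1.02, 0.984 to 1.05), and its ratio with all named subtypes weighted equally was 1.01. Oprm1 had a higher CPM in 5 of 10 named subtypes. It was lower in A-delta LTMR-like neurons (324 and 62 UMIs, ratio 0.324, 0.243 to 0.426), C-LTMR-like neurons (0.604, 0.468 to 0.776) and the unnamed neuron cluster (0.598, 0.449 to 0.787). Oprd1, the delta receptor, was at 11.4 and 10.2 CPM (0.895, 0.836 to 0.957), and equal weighting turned this direction. It had a higher CPM in 4 of 10 named subtypes, among them A-beta LTMR-like neurons, its highest subtype (29.9 and 38.4 CPM, 1.29, 1.09 to 1.52). In peptidergic C-like neurons it had 15 and 3 UMIs (0.238, 0.0442 to 0.843). Oprk1, the kappa receptor, was at 1.42 and 1.74 CPM (1.23, 1.03 to 1.46), a direction that turned when each neuron counted equally, and Oprl1, the nociceptin receptor, was at 16.1 and 15.5 CPM (0.963, 0.911 to 1.02). Over all cells, the peptide precursor gene Pdyn had 26 UMIs in each library and was at 0.1003 and 0.166 CPM (1.66, 0.924 to 2.97), Pnoc was at 0.899 and 1.19 CPM (1.32, 1.08 to 1.61) and Pomc at 3.01 and 3.12 CPM (1.04).

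The makeup of the ganglia by cell class was close in both libraries. Neurons were 42.2% of control cells (41.4 to 43.0) and 42.2% of Treg_Penk_KO cells (41.3 to 43.1). Myelinating Schwann-like cells were 16.8% and 16.4%, satellite glia-like cells, which wrap the neuron bodies, 12.3% and 11.9%, fibroblast-like cells 6.58% and 6.58%, and macrophage-like cells 4.65% and 4.95%. Mural-like cells, the contractile cells of vessel walls, had the largest ratio away from 1 among the named classes, 1.40% (1.22 to 1.59) against 1.05% (0.872 to 1.24), or 219 and 126 cells. Endothelial-like cells were 3.79% (3.50 to 4.10) and 4.21% (3.86 to 4.59).

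Of the unnamed clusters, the cells led by Igfbp6, Islr and Thbs4 were 3.75% (3.46 to 4.06) and 4.42% (4.06 to 4.80), those led by the globin genes Hbb-bs and Hba-a2 were 5.40% and 5.11%, and another was 2.85% and 2.65%. The endothelial-like ratio of 1.11 turned to 0.937 in droplets holding a cell of 1 library only, a setting chosen after the data were seen. Median depth was 11151.5 and 7874 UMIs per neuron, 1865 and 1692.5 per myelinating Schwann-like cell and 3142 and 3276 per endothelial-like cell.

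**Figure D2:**
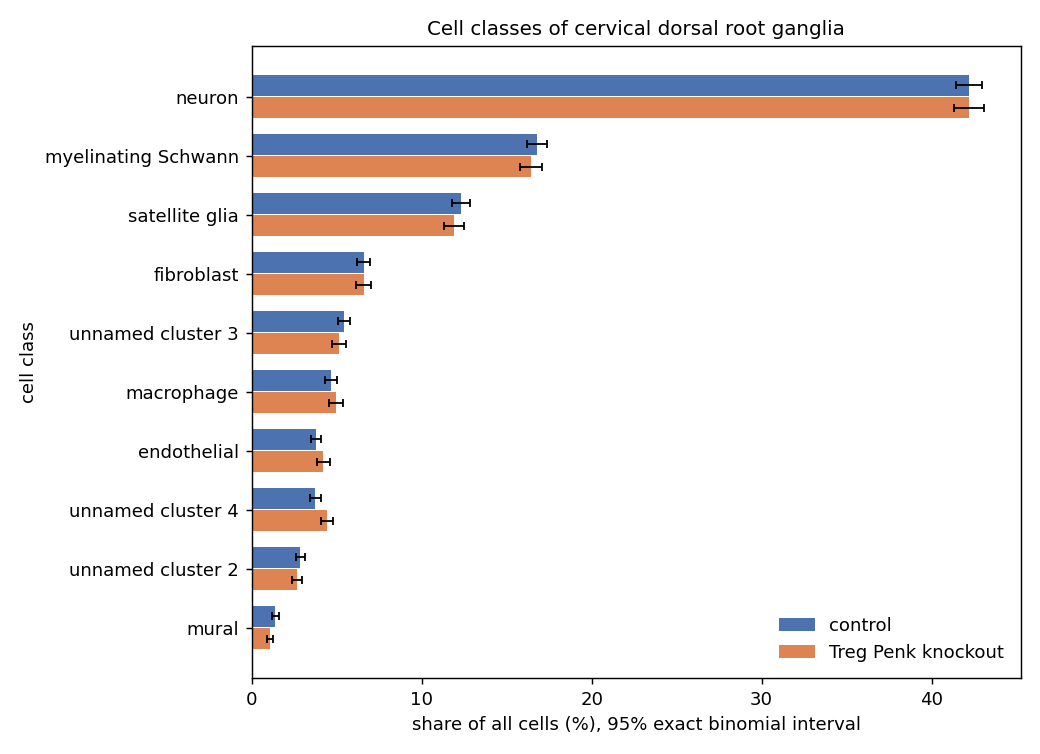
Share of all kept cells in each cell class (bars, percent, axis from 0) in the control and Treg_Penk_KO libraries, with exact binomial 95% intervals. Neurons are at 42.2% in both, and mural-like cells at 1.40% and 1.05%.

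Within the neurons, 1 cluster of the peptidergic A-fibre-like cells, fast nociceptors that carry the CGRP gene Calca, made up a smaller share in the Treg_Penk_KO library and peptidergic C-like cells made up a larger share. The peptidergic A-fibre-like share was 14.1% of 6620 control neurons (13.2 to 14.9) and 11.1% of 5085 Treg_Penk_KO neurons (10.2 to 11.99). Of these cells, 336 and 89 came from a single cluster with the glial gene Apoe among its top genes, and without it the share was 9.003% (8.32 to 9.72) and 9.34% (8.56 to 10.2). The peptidergic C-like share was 9.65% (8.95 to 10.4) and 11.5% (10.7 to 12.4). A-beta LTMR-like neurons, touch neurons with thick myelinated fibres, were 3.79% (3.34 to 4.28) and 4.52% (3.97 to 5.13), and A-delta LTMR-like neurons 3.58% (3.15 to 4.06) and 3.05% (2.59 to 3.56).

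The intervals of both libraries overlapped for these LTMR-like shares and for the remaining subtypes. Proprioceptor-like neurons were 20.8% and 20.0%, Mrgprd nonpeptidergic-like neurons 20.5% and 21.6%, C-LTMR-like neurons 7.36% and 7.24%, Sst/Nppb pruriceptor-like neurons, which signal itch, 5.38% and 5.76%, Mrgpra3 pruriceptor-like neurons 5.00% and 5.09%, and Trpm8 cold-like neurons 3.32% and 3.62%. An unnamed neuron cluster was 5.57% and 5.62%. In droplets with a cell of 1 library only, the A-delta LTMR-like ratio turned from 0.851 to 1.09 and the Mrgprd nonpeptidergic-like ratio from 1.05 to 0.959.

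**Figure D3:**
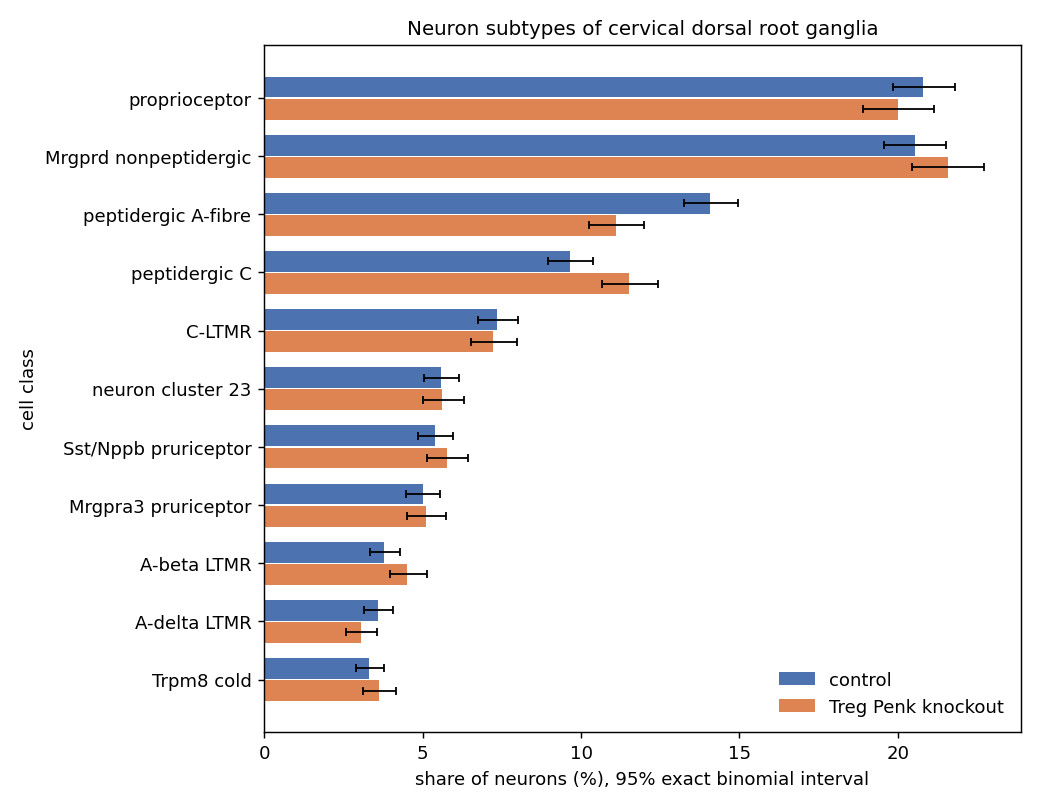
Share of neurons in each subtype (bars, percent, axis from 0) in both libraries, with exact binomial 95% intervals. Peptidergic A-fibre-like neurons are at 14.1% and 11.1%, and peptidergic C-like neurons at 9.65% and 11.5%.

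Over all neurons, the median of the itch list was higher in the Treg_Penk_KO library and that of the immediate early list lower. Pruriceptor-like and peptidergic C-like neurons also gave a larger share of neuronal UMIs in that library, and the itch median was close to that of no difference when subtypes were weighted equally. Differences were small for most genes, as 99.3% of 7157 eligible genes differed by less than the size step, a ratio of 25% above 1 or its inverse.

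The 10 eligible genes with the highest ratios included 5 members of the itch list. Mrgprb4, a receptor of neurons that respond to stroking, was at 60.5 and 103 CPM (ratio 1.71, 1.67 to 1.75), and Nppb, the peptide that relays itch to the spinal cord, at 33.1 and 48.7 CPM (1.47, 1.42 to 1.52). Il31ra and Osmr, which together form the receptor of the itch cytokine interleukin 31, were at 50.5 and 71.8 CPM and at 54.2 and 77.0 CPM (both 1.42, 1.38 to 1.46). Cysltr2, a leukotriene receptor, was at 24.9 and 34.0 CPM (1.37), Th, the tyrosine hydroxylase of C-LTMR neurons, at 86.4 and 120 CPM (1.39), Mlc1 at 20.0 and 27.9 CPM (1.39), and Cbln1, a synapse organiser, at 14.6 and 20.9 CPM (1.43, which turned with thinned cells). The other 2 were Snapc1, a subunit of the complex that transcribes small nuclear RNA genes, at 32.6 and 49.4 CPM (1.52, 1.46 to 1.57), and Tmem68 at 22.1 and 31.5 CPM (1.43, 1.37 to 1.49).

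The 10 lowest were led by Cc2d1b, a gene of the membrane-remodelling machinery, at 52.3 and 29.0 CPM (ratio 0.554, 0.534 to 0.575), Tmem267 at 46.7 and 26.6 CPM (0.570, 0.548 to 0.593) and the X-linked Rtl8b at 98.4 and 58.5 CPM (0.595, 0.579 to 0.611). Below these in size were Calb1 and Calb2, which encode calcium-binding proteins, at 42.4 and 30.3 CPM (0.714) and at 24.96 and 18.3 CPM (0.735). A single cell held 16.5% of the control and 17.6% of the Treg_Penk_KO UMIs of Calb2, and its direction turned with thinned cells. Inha, an inhibin subunit, had a ratio of 0.723, Snhg11, a long noncoding RNA of neurons, 0.738 (255 and 188 CPM), the cold-inducible Cirbp 0.747, the elongation factor Supt5 0.775 and Osbp2 0.785.

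Several of these genes mark subtypes, and the share of neuronal UMIs from each subtype differed between the libraries. Sst/Nppb pruriceptor-like neurons gave 2.84% of neuronal UMIs in the control and 3.96% in the Treg_Penk_KO library, Mrgpra3 pruriceptor-like neurons 4.80% and 6.64%, peptidergic C-like neurons 4.98% and 6.98% and C-LTMR-like neurons 4.91% and 5.91%, while proprioceptor-like neurons gave 24.5% and 21.1%. With subtypes weighted equally the ratios were 1.2514 for Mrgprb4, 1.07 for Nppb, 1.05 for Il31ra, 1.07 for Osmr, 1.06 for Cysltr2 and 1.20 for Th, all of which served as subtype markers. Within Mrgpra3 pruriceptor-like neurons, its highest subtype, Mrgprb4 had a ratio of 1.28 (1.248 to 1.31). This subtype joins a cluster led by Mrgprb4 (166 and 140 cells, median 15370 and 18253 UMIs) and another (165 and 119 cells, 14066 and 12016 UMIs). Another mix of these clusters was not told apart from a higher level per cell. Of the sensory genes fixed in advance, Calca was at 419 and 506 CPM (1.21, 1.20 to 1.22) and 1.07 with equal weights, the substance P gene Tac1 at 212 and 267 CPM (1.26) and 1.04, the capsaicin receptor Trpv1 at 69.2 and 89.4 CPM (1.29) and 1.02, and the irritant receptor Trpa1 at 70.5 and 84.2 CPM (1.20) and 1.03, with Trpa1 turning in thinned cells. Snapc1 and Tmem68 were higher in 10 of 10 named subtypes, whereas Cc2d1b, Tmem267, Rtl8b, Cirbp, Snhg11, Inha and Supt5 were lower in all 10, although Rtl8b turned with thinned cells in peptidergic A-fibre-like neurons.

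Of the 31 gene lists fixed in advance, the itch list stood highest in neurons and, apart from the red blood cell genes, the immediate early list lowest. Of 27 measured itch receptors and mediators, 11 were higher and 0 lower by at least the size step, with a median ratio of 1.20 (log2 0.26; random lists of matched expression -0.05 to 0.04). Examples were Mrgpra3, a receptor for chloroquine itch, at 5.66 and 9.37 CPM, the somatostatin gene Sst at 6.21 and 9.51 CPM, Mrgprd at 192 and 237 CPM and the phospholipase Plcb3 at 398 and 444 CPM. With subtypes weighted equally the median log2 ratio of the itch list was 0.02. Of 30 immediate early genes, which stimulated neurons switch on within minutes, 0 were higher and 9 lower, with a median ratio of 0.853 (log2 -0.23; random lists -0.10 to 0.04), and the median was -0.13 with thinned cells. Egr1 was at 19.9 and 11.9 CPM (0.599, 0.565 to 0.635), Egr3 at 5.56 and 3.01 CPM (0.541), Fos at 7.07 and 4.32 CPM (0.611, 0.554 to 0.674), Npas4 at 0.273 and 0.0929 CPM (0.340) and the phosphatase Dusp1 at 41.2 and 34.0 CPM (0.824), while Jun (0.984) and Jund (0.973) were close to 1. Atf3, a marker of nerve injury, had a ratio of 0.9499 (0.904 to 0.998), which turned under 3 settings. Egr1 was highest in fibroblast-like and Egr3 in satellite glia-like cells, and RNA of such cells was not taken out of the neuronal values.

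Genes induced by glucocorticoids were also lower as a list. Of 23 measured, 0 were higher and 7 lower, with a median ratio of 0.875 (log2 -0.19; random lists -0.06 to 0.04). The metallothioneins Mt1 and Mt2 were at 135 and 102 CPM (0.753) and at 64.9 and 43.6 CPM (0.671), and the lipid droplet gene Plin4 at 6.52 and 4.01 CPM (0.615), while Fkbp5 was at 80.2 and 83.9 CPM (1.05) and Tsc22d3 at 145 and 137 CPM (0.946). The median log2 ratio was -0.05 with thinned cells. Plin4 was highest in an unnamed cluster outside the neurons, and RNA of such cells was not taken out here either. The circadian list had 3 of 20 genes lower and 0 higher (median ratio 0.915, with Dbp at 0.788), and the hypoxia and glycolysis list 2 of 21 lower (0.965, with Ndrg1 at 0.833 and Egln3 at 0.772).

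The interferon response list had 6 of 38 genes higher and 1 lower, with a median ratio of 1.097 (log2 0.13; random lists -0.04 to 0.03). Rsad2, the antiviral viperin, was at 22.3 and 32.9 CPM (1.47, 1.41 to 1.54), Ifit1 at 315 and 358 CPM (1.14) and Ifit3b at 14.4 and 18.7 CPM (1.30), while the abundant Oasl2 was at 403 and 410 CPM (1.02). Its median log2 ratio was 0.07 with thinned cells and with equal weights.

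Other lists outside their random ranges had medians on either side of a ratio of 1. Neuropeptides had 9 of 27 higher and 3 lower (median ratio 1.14) and axon injury and regeneration genes 7 of 31 higher and 2 lower (1.07, with the growth cone gene Gap43 at 1.11 and Sprr1a at 3.56 and 5.39 CPM, or 2.97 and 1.13 CPM without a cluster of 14 and 12 cells), and both medians turned below 1 with equal weights. In the nociceptive transduction and sodium channel list 4 of 40 were higher and 0 lower (1.06), with the nociceptor sodium channel Scn10a at 863 and 976 CPM and Scn2b at 95.8 and 124 CPM. Gi and cAMP signalling had 2 of 40 higher (1.04, with Rgs4 at 772 and 958 CPM), cholesterol synthesis 0 of 25 higher and 1 lower (1.03, which turned with equal weights) and the mitochondrially encoded genes 0 of 13 past the step (1.04). Potassium channels had 2 of 42 lower (0.980, which turned at the coarser clustering), with Kcna1 at 354 and 295 CPM (0.834) and Kcnc1 at 103 and 82.0 CPM (0.798).

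The lists of the surrounding glia were lower in neurons. Satellite glia reactivity genes had 2 of 26 higher and 5 lower (median ratio 0.897), with the lipid carrier Apoe at 1213 and 883 CPM (0.728). Myelin genes had 1 of 20 higher and 3 lower (0.874). Markers of other cells moved with these lists, as satellite glia markers were 0.275% of neuronal UMIs in the control and 0.234% in the Treg_Penk_KO library and Schwann markers 0.104% and 0.0997%. The medians of both lists came close to 0 on the log2 scale with thinned cells, at -0.02 and -0.06.

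The other 15 lists lay inside the range of their random lists in neurons. These were delayed activity genes (median ratio 0.979), opioid peptides, receptors and peptidases (0.998), cytokine and growth factor receptors (1.01), inflammatory cytokines and chemokines (0.968), the Schwann repair programme (0.984), extracellular matrix (0.970), MHC class II antigen presentation (0.963), macrophage activation (1.01), regulatory T cell genes (1.05, 6 of 17 measured), heat shock (1.02), oxidative phosphorylation (0.993), synaptic vesicle genes (0.991), the cytoskeleton (0.991), apoptosis (0.954) and the sex-linked genes (1.01).

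**Figure D4:**
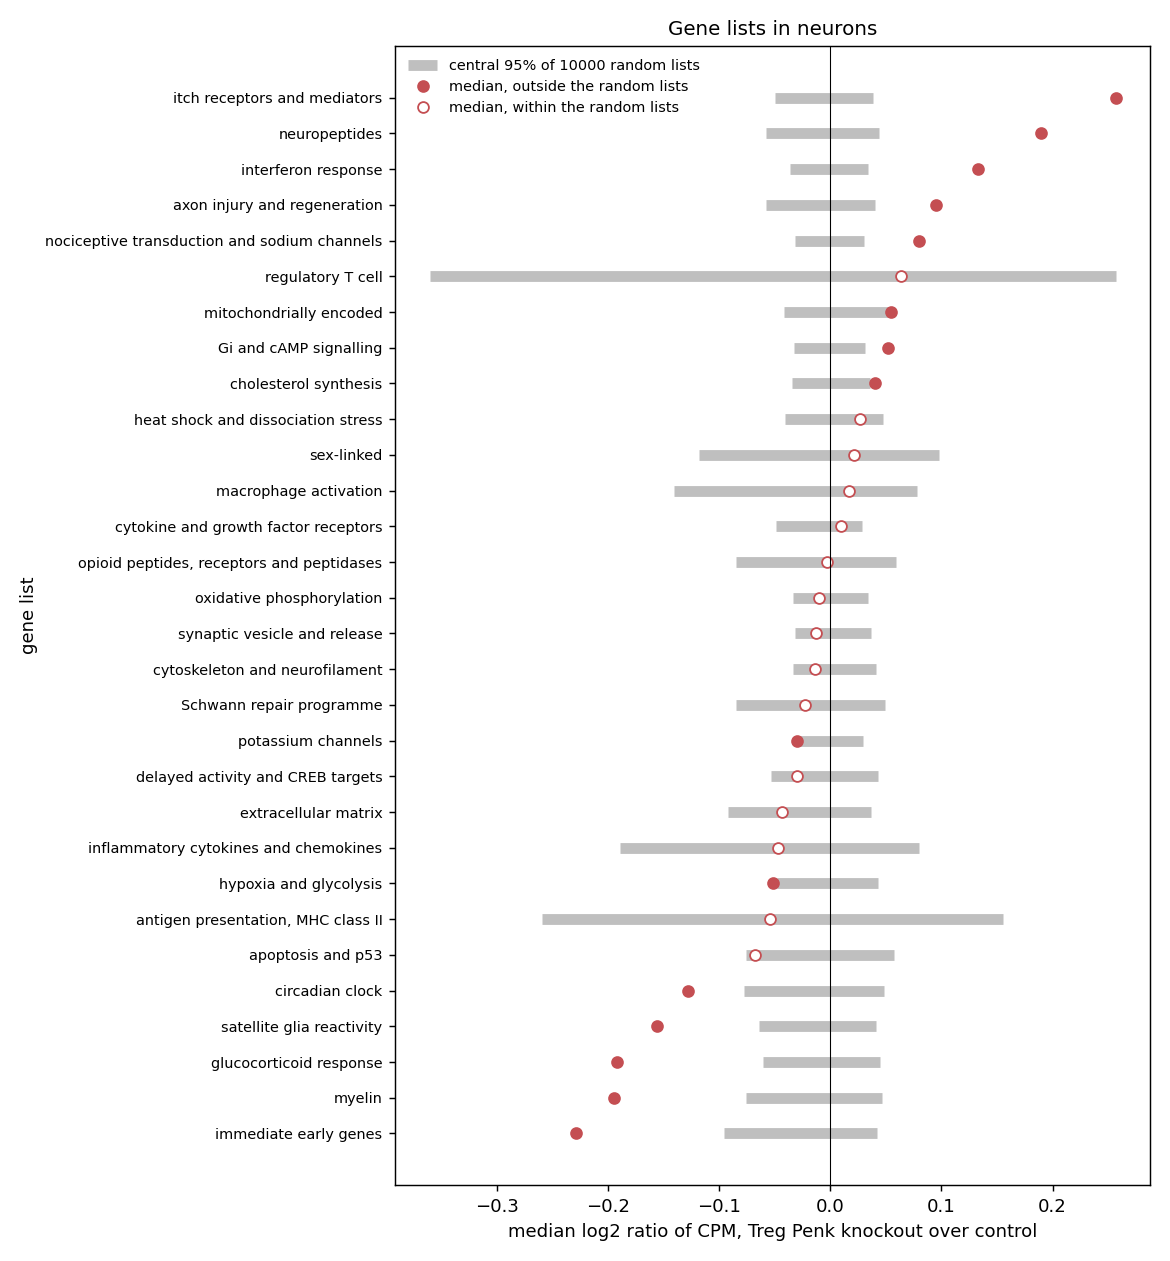
Median log2 ratio of Treg_Penk_KO to control in neurons for 30 of the fixed gene lists (points; filled where the median lies outside the central 95% of 10000 random lists, which the grey bars show). The itch list is at 0.26 and the immediate early list at -0.23; the red blood cell list, at -0.84, is left out.

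The immediate early median lay below the random lists in 7 of the 10 named subtypes, and differences between subtypes were not tested. Trpm8 cold-like neurons had the lowest median, with 16 of 21 measured genes lower and 0 higher (log2 -0.78), followed by A-delta LTMR-like (15 of 22 lower, -0.51) and peptidergic C-like neurons (13 of 23 lower and 1 higher, -0.37). Above these were peptidergic A-fibre-like (14 of 27 lower, -0.34), A-beta LTMR-like (-0.26), Mrgprd nonpeptidergic-like (-0.21) and proprioceptor-like neurons (-0.16). C-LTMR-like, Mrgpra3 and Sst/Nppb pruriceptor-like neurons lay inside the random range, at -0.11, -0.13 and -0.17, and Egr1 was higher in the last (16.3 and 25.01 CPM, 1.53, 1.17 to 2.01). Fos in Trpm8 cold-like neurons was at 51.1 and 7.61 CPM (0.149, 0.0813 to 0.253), with 64.1% of the control UMIs in 1 cell, and Egr1 in peptidergic C-like neurons at 12.2 and 4.77 CPM (0.391). The list turned in Trpm8 cold-like neurons with members of at least 200 UMIs (0.01), in peptidergic C-like neurons with thinned cells (0.14) and in proprioceptor-like neurons in droplets of 1 library (0.10).

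Glucocorticoid-induced genes were below the random lists in 9 of the 10 named subtypes, from A-beta LTMR-like (12 of 22 lower and 1 higher, -0.38) and A-delta LTMR-like (11 of 20 lower, -0.34) to Mrgpra3 pruriceptor-like (-0.15) and proprioceptor-like neurons (-0.06), with Sst/Nppb pruriceptor-like neurons at -0.04. The direction turned for C-LTMR-like and proprioceptor-like neurons under other settings. The interferon list was higher in peptidergic C-like and C-LTMR-like neurons (both 0.18) and in Mrgprd nonpeptidergic-like (0.12), A-beta LTMR-like (0.12), peptidergic A-fibre-like (0.11) and Mrgpra3 pruriceptor-like neurons (0.10), and lower in A-delta LTMR-like neurons (18 of 34 lower, -0.35) and the unnamed neuron cluster (20 of 36 lower, -0.33). In peptidergic C-like neurons the ubiquitin-like Isg15 was at 25.03 and 36.3 CPM (1.45) and Ifit3 at 66.8 and 94.9 CPM (1.42), while in A-delta LTMR-like neurons Ifit1 was at 116 and 63.9 CPM (0.554). With thinned cells the list turned in peptidergic C-like, peptidergic A-fibre-like and A-beta LTMR-like neurons.

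Car8 had the lowest ratio of the eligible genes in 3 subtypes. This gene, a relative of the carbonic anhydrases, was at 79.0 and 18.8 CPM in peptidergic C-like neurons (ratio 0.239, 0.201 to 0.282), 43.2 and 11.1 CPM in Sst/Nppb pruriceptor-like neurons (0.258, 0.18997 to 0.344) and 80.8 and 35.9 CPM in Mrgpra3 pruriceptor-like neurons (0.445, 0.389 to 0.507). Olfr920, an odorant receptor gene, was at 21.9 and 7.54 CPM in peptidergic C-like neurons (0.345) and had a ratio of 0.460 in Mrgpra3 pruriceptor-like neurons. Ccl2, a chemokine that recruits monocytes, was at 28.4 and 15.3 CPM in peptidergic C-like neurons (0.539, 0.438 to 0.662), where Mettl16 was higher (1.61) and the somatostatin receptor Sstr1 was at 31.3 and 47.9 CPM (1.53), which turned when each cell counted equally.

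Among the genes that were higher, Gpx2, a glutathione peroxidase, was at 20.1 and 36.1 CPM in C-LTMR-like neurons (1.80, 1.496 to 2.16), and Cfap61 at 41.3 and 68.9 CPM (1.67) and Mab21l1 at 1.65 in Mrgpra3 pruriceptor-like neurons. Peptidergic A-fibre-like neurons had Prokr2 at 17.1 and 28.2 CPM (1.65) and Diaph3 at 1.57, and A-delta LTMR-like neurons Necab1 at 54.5 and 81.8 CPM and Arid4b at 1.48. In Trpm8 cold-like neurons Kctd1 (1.76), Cyb561d2 (1.72) and Sdf2l1 (1.62) were higher and Exosc8 was lower (0.440). Nav2 was higher in proprioceptor-like (17.3 and 29.8 CPM, 1.72), C-LTMR-like (1.71) and A-beta LTMR-like neurons (1.70). Ifit1bl1 in Mrgprd nonpeptidergic-like neurons was at 11.7 and 27.3 CPM (2.33), with 27.5% of the Treg_Penk_KO UMIs in 1 cell. In A-beta LTMR-like neurons Ramp3 (2.04) and Syt13 (1.86) turned when each cell counted equally, and Atf3, at 23.3 and 3.55 CPM, had 58.7% of its control UMIs in 1 cell. Sst/Nppb pruriceptor-like neurons had Urb2 at 1.59, Rbmx at 0.540 and Zc3h6 at 0.551. C-LTMR-like neurons had Ppfia3 at 0.530 and A-beta LTMR-like neurons Sema6a at 0.562. Cidea in proprioceptor-like neurons, at 1.51, turned with thinned cells.

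Satellite glia-like cells had lower medians of the immediate early and glucocorticoid-induced lists, and Egr1 was among their lowest genes. Egr1 was at 217 and 112 CPM (ratio 0.516, 0.478 to 0.557), so in the control library it was far above its 19.9 CPM in neurons. Of 27 immediate early genes 8 were lower and 0 higher (median log2 -0.16, random lists -0.07 to 0.07), with Zfp36 at 65.8 and 44.6 CPM (0.678), Junb at 25.4 and 17.3 CPM (0.681) and Nr4a1 at 366 and 361 CPM (0.987), and the median turned at the coarser clustering. Of 23 glucocorticoid-induced genes 5 were lower and 1 higher (-0.20, random lists -0.06 to 0.06), with Plin4 at 77.0 and 44.0 CPM (0.572) and the kinase Sgk1 at 61.7 and 45.2 CPM (0.733). Clock genes had 3 of 20 lower and 0 higher (-0.12), with Per2 at 22.3 and 12.9 CPM (0.580).

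The genes with the highest ratios were Calb2 at 8.73 and 34.1 CPM, with 70.7% of the Treg_Penk_KO UMIs in 1 cell and a direction that turned with the top-scoring doublets removed (log2 1.96 to -0.86), Trpa1 at 19.2 and 38.4 CPM (2.003, 1.69 to 2.37; 24% in 1 cell) and Myo1a at 1.59. Below these came the glutamate transporter Slc1a2 at 14.8 and 23.2 CPM (1.57, 1.27 to 1.93, which turned with thinned cells), Dhrs2 at 32.2 and 48.3 CPM (1.497) and the transcription factor Tcf3 at 26.6 and 39.8 CPM (1.49). The lowest besides Egr1 were Cc2d1b (0.526), Epop (22.2 and 11.9 CPM, 0.537), Tmem267 (0.558), Lhfpl1 (0.584) and Rtl8b (0.594). Inflammatory cytokines and chemokines had 10 of 20 higher and 2 lower (0.34), with Ccl4 at 1.19 and 3.71 CPM and the alarmin S100a9 at 1.34 and 3.20 CPM, and the list turned under 4 settings. Satellite glia reactivity genes had 3 of 26 higher and 1 lower (0.07), with the intermediate filament gene Vim at 5031 and 6163 CPM (1.23) and Gfap at 6.34 and 10.1 CPM (1.59). Cholesterol synthesis genes had 0 of 25 past the step (0.08), extracellular matrix genes 5 of 31 higher and 1 lower (0.09) and interferon genes 4 of 37 higher and 0 lower (0.06). Of the UMIs of this class, 86.8% and 82.7% came from 1 cluster of 508 and 320 cells with a median of 16585.5 and 14352.5 UMIs. Neuron markers made up 0.935% and 0.868% of the class's UMIs, and 1.48% and 1.43% of those of the myelinating Schwann-like cells, against 2.22% and 2.16% in neurons themselves. The itch list, at 0.14 here and turned under 3 settings, holds the neuron genes Mrgprd (41.8 and 64.9 CPM) and Mrgprb4. It also holds Trpa1, which was at 241 and 238 CPM in Mrgprd nonpeptidergic-like neurons, its highest neuron subtype. Neuron markers reached up to 0.472 and 0.465 of their neuronal level in satellite glia-like cells. The higher Trpa1 ratio in this class thus cannot be told apart from RNA of neurons.

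Several lists of neuronal genes had lower medians in the same cells, as did the share of neuron markers, while the itch list was at 0.14. Synaptic vesicle genes were at -0.13 (1 of 26 lower), delayed activity genes at -0.12 (4 of 23 lower and 2 higher) and neuropeptides at -0.12 (4 of 20 lower and 1 higher). Potassium channels were at -0.09 (7 of 42 lower and 2 higher) and nociceptive channels at -0.06. The cytoskeleton and the hypoxia and glycolysis lists, which are not limited to neuronal genes, were each at -0.10.

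Myelinating Schwann-like cells had higher medians of the extracellular matrix and macrophage activation lists and lower medians of the clock and immediate early lists. Of 31 matrix genes 16 were higher and 0 lower (median log2 0.33, random lists -0.05 to 0.05), with the fibronectin gene Fn1 at 34.6 and 61.3 CPM (1.77, 1.59 to 1.97), Col6a2 at 24.3 and 42.2 CPM (1.73) and Dcn at 602 and 749 CPM (1.24). In fibroblast-like cells Dcn was at 9665 and 10032 CPM, and fibroblast markers made up 0.697% and 0.748% of the Schwann class's UMIs, with 0.533% and 0.649% in the cluster that gave most of these UMIs and 1.81% and 1.51% in another. Macrophage activation genes had 9 of 17 higher and 0 lower (0.32), with F13a1 at 7.89 and 12.4 CPM (1.57) and Plac8 at 0.345 and 1.77 CPM. Macrophage markers made up 0.0301% and 0.0420% of these UMIs. Myelin genes, which overlap the markers that named the class, were at 0.20, and the list turned with deeper cells only and with the top-scoring doublets removed.

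Clock genes in these cells had 5 of 20 lower and 1 higher (-0.17), with Per3 at 10.8 and 6.37 CPM (0.589), and immediate early genes 6 of 28 lower and 0 higher (-0.10), with Egr1 at 65.0 and 42.8 CPM (0.658). The highest single genes were the protease inhibitor Spint1 at 14.3 and 23.2 CPM (1.62, 1.37 to 1.93), Nav2 at 26.6 and 42.8 CPM (1.61, 1.42 to 1.82) and Emid1 at 26.3 and 38.9 CPM (1.48). The lowest were Cc2d1b at 54.2 and 26.6 CPM (0.491), Tmem267 (0.597) and Rtl8b (0.622). Inflammatory cytokines were at 0.26 (7 of 20 higher and 1 lower, with Ccl2 at 5.23 and 10.4 CPM), a direction that turned with thinned cells. Satellite glia reactivity genes were at 0.12, interferon genes at 0.12 (3 of 38 higher and 0 lower) and the Schwann repair programme at 0.11 with Gap43 at 270 and 350 CPM (1.29). Apoptosis genes were at -0.07, potassium channels at -0.07, the cytoskeleton at -0.06 and synaptic vesicle genes at -0.05. A cluster of 911 and 697 cells gave 83.5% and 82.2% of this class's UMIs with myelinating Schwann markers at only 0.946% and 1.13% of its UMIs, against 6.38% and 7.43% in a cluster of 982 and 710 cells.

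Endothelial-like cells had lower immediate early and glucocorticoid-induced genes as lists. Depp1, a target of FOXO factors, was at 66.3 and 20.4 CPM (ratio 0.308, 0.235 to 0.399), the leukocyte adhesion gene Icam1 at 25.5 and 10.6 CPM (0.417, 0.281 to 0.608) and Kcnk12 at 24.98 and 11.2 CPM (0.447). Of 26 immediate early genes 12 were lower and 0 higher (median log2 -0.28, random lists -0.09 to 0.08), with Ier3 at 130 and 65.9 CPM (0.507) and Egr1 at 79.9 and 48.5 CPM (0.607). Of 23 glucocorticoid-induced genes 5 were lower and 0 higher (-0.17), with Sgk1 at 150 and 112 CPM (0.746). MHC class II genes had 4 of 8 higher and 1 lower (0.53), with the invariant chain Cd74 at 17.3 and 46.6 CPM (2.69, 2.03 to 3.60). Macrophage markers, foreign to this class, made up 0.0633% and 0.0704% of its UMIs. Interferon genes had 3 of 37 higher and 1 lower (0.13), with Ifi44 at 80.1 and 111 CPM. Heat shock genes were at 0.16, with Hspa1b at 19.3 and 28.6 CPM (1.48). Myelin genes, foreign to this class, had 10 of 20 lower and 0 higher (-0.33), and Schwann markers made up 0.984% and 0.755% of its UMIs.

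The 3 highest genes of this class were immunoglobulin genes that rest on 1 Treg_Penk_KO cell, with Igkc at 3 and 776 UMIs, Igha at 0 and 185 and Igkv15-103 at 0 and 119. This cell held 4 of the 171 Cd74 UMIs, and the MHC class II median was 0.53 without it. The remaining lists outside the random range were apoptosis (-0.16), cholesterol synthesis (-0.14), itch (-0.14, which turned with the top-scoring doublets removed), macrophage activation (-0.13), the cytoskeleton (0.11), synaptic vesicle genes (0.11) and extracellular matrix (0.08). Neuron markers were also higher in this class, at 1.082% and 1.26% of its UMIs.

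Fibroblast-like cells had a higher median of the matrix genes. Of 31 measured, 12 were higher and 2 lower (median log2 0.30, random lists -0.09 to 0.07), with Fn1 at 502 and 1349 CPM (2.69, 2.46 to 2.94; 15.5% of the Treg_Penk_KO UMIs in 1 cell), the protease inhibitor Timp1 at 17.5 and 74.3 CPM (4.25, 2.69 to 6.93) and the collagens Col3a1 (1.29) and Col1a1 (1.23), both of which served as fibroblast markers. The collagen hydroxylase gene Plod3 was at 84.8 and 197 CPM (28.6% in 1 cell) and S100a4 at 52.5 and 118 CPM (22.0% in 1 cell). The lowest were Lrpprc at 75.7 and 35.8 CPM (0.474), Ccp110 (0.528) and Nsmaf (0.559). Immediate early genes had 8 of 25 lower and 1 higher (-0.20), with Fos at 30.8 and 17.0 CPM (0.552), and clock genes 5 of 18 lower and 1 higher (-0.20), with Cry1 at 33.6 and 14.3 CPM. Mitochondrially encoded genes were at -0.19, potassium channels at -0.14, cholesterol synthesis at -0.14, oxidative phosphorylation at -0.10, heat shock genes at 0.15 and apoptosis genes at 0.18, the last turning under 3 settings.

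Macrophage-like cells had higher Lipg, the endothelial lipase gene, at 39.5 and 113 CPM (ratio 2.86, 2.03 to 4.09), and higher Ccl4, at 37.8 and 90.6 CPM (2.40, 1.67 to 3.49), and the B cell attractant Cxcl13, at 94.9 and 178 CPM (1.87, 1.48 to 2.38). Inflammatory cytokines and chemokines as a list had 5 of 16 higher and 5 lower (median log2 -0.018, inside the random range of -0.14 to 0.15). The acute-phase gene Saa3 was at 719 and 204 CPM (0.284; 15.1% and 31.1% in 1 cell of each library), Chil3 at 94.0 and 44.8 CPM (58.0% and 46.0% in 1 cell) and Vgf at 280 and 151 CPM (0.539, 0.445 to 0.650). Glucocorticoid-induced genes had 6 of 20 lower and 1 higher (median log2 -0.25, random lists -0.12 to 0.12), with Fkbp5 at 190 and 134 CPM (0.704), and clock genes 5 of 16 lower and 2 higher (-0.23). Interferon genes had 9 of 36 higher and 1 lower (0.11), with Isg15 at 71.4 and 117 CPM (1.63). Myelin genes (0.32, 10 of 20 higher and 1 lower, with Mbp at 493 and 846 CPM) and satellite glia reactivity genes (0.15, with Fabp7 at 238 and 437 CPM) are products of glia, and Schwann markers made up 0.387% and 0.471% of these UMIs. Cytokine receptors were at -0.15 and axon injury genes at -0.16, the latter turning in droplets of 1 library.

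Mural-like cells, the smallest class compared, had Map7d2 at 425 and 674 CPM (25.6% in 1 cell), Rhob, a small GTPase, at 783 and 1145 CPM (1.46, 1.17 to 1.82) and Ifitm2 at 1.41. Lower in this class were Ldhb at 499 and 284 CPM (0.570, 0.385 to 0.827), Tmem30a (0.617) and Cygb, the cytoglobin gene, at 0.635. Glucocorticoid-induced genes had 7 of 17 lower and 1 higher (median log2 -0.24, random lists -0.20 to 0.30), with Mt1 at 239 and 142 CPM, and the mitochondrially encoded genes had a median ratio of 0.898.

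Red blood cell genes were lower in the Treg_Penk_KO library. Over all cells the beta-globin gene Hbb-bs was at 17.1 and 4.79 CPM (ratio 0.281, 0.259 to 0.303), Hba-a2 at 10.1 and 4.80 CPM (0.474), Hbb-bt at 3.74 and 0.914 CPM (0.245) and the heme synthesis gene Alas2 at 0.606 and 0.205 CPM (0.338), while Hba-a1 was at 1.36 and 1.22 CPM (0.899, 0.7497 to 1.07) and Slc4a1 had 40 and 5 UMIs. In neurons 4 of 5 measured were lower (median log2 -0.84), and the median was -1.65 with at least 1500 UMIs per cell, -0.31 at the coarser clustering, -0.32 with equal weights and -0.0945 in droplets with a cell of 1 library, a setting chosen after the data were seen. The list was also lower in endothelial-like (-2.42), satellite glia-like (-1.09, which turned when each cell counted equally) and myelinating Schwann-like cells (-0.59), and the size of these medians also moved between settings.

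The Y-linked genes were at close levels in both pools. Ddx3y was at 62.4 and 62.2 CPM, Eif2s3y at 38.3 and 41.1, Kdm5d at 10.99 and 11.4 and Uty at 30.5 and 28.9, and 4 of the 6 sex-linked genes fixed in advance were in the probe panel.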

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

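All 12 tests of explanations below were chosen after the results they bear on had been seen.

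Penk UMIs were almost absent from every cell class of the Treg_Penk_KO library that had enough counts to compare, although the genotype deletes the gene in cells that express Foxp3. Lower depth would have left 351.4 UMIs at the control CPM, and fewer cells of the classes that hold Penk 369.5 UMIs, against 4 seen with an upper end of 10.2, so neither accounts for the loss. Of 12 classes or subtypes with at least 5 expected UMIs, 9 had a ratio whose upper end was below 0.5, among them Trpm8 cold-like neurons, glia, endothelial-like and fibroblast-like cells, and the other 3, the Sst/Nppb, peptidergic A-fibre-like and peptidergic C-like neurons, had too few counts. A candidate explanation is that the Penk signal of the floxed allele was lost outside Foxp3 cells, by recombination there or because the probes do not read it, and these cannot be told apart from each other because the probe positions and the recombined allele were not analysed here. A biological effect of the genotype on Penk in these cells was not tested and stays open.

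A set of 48 genes out of 11293 measured in neurons, satellite glia-like and myelinating Schwann-like cells differed alike in all 3 classes, 22 higher and 26 lower, with Cc2d1b (4:108476527 to 108492884), Tmem267 (13:119624575 to 120072595), Ccl28 (13:120085355 to 120115895), Rtl8b (X:52671141 to 52680104), Ppfia3 (7:44988545 to 45016901) and Nav2 (7:48558464 to 49259838) among them (Ccl28 was chosen after its values were seen). RNA from other cells cannot be told apart from a shift of their own. Neuron markers reached up to 0.472 of their neuronal level in satellite glia-like and up to 0.775 in myelinating Schwann-like cells. With that much neuronal RNA taken away, 3 of the 19 genes with at least 0.25 of their highest level in all 3 classes kept their direction beyond counting error in both glial classes. These were Cc2d1b, Cirbp and Gng5, the last chosen after its values were seen. Of the other 29 genes, 27 differed the same way, by any size, in the class where they were highest. For those highest in satellite glia-like cells, Nav2 among them, the selection had fixed that outcome. Of the 30 genes with such a level in at least 1 of the 3 classes, 10 had another within 2 Mb against a median of 2 in random sets, and 4, 16, 16 and 18 had one within 1, 5, 10 and 20 Mb against 2, 4, 7 and 12, so chromosome segments of another haplotype in 1 pool may contribute but did not stand out at the shortest and longest distances. Within 5 Mb of Penk, 3 of the 12 genes with at least 100 UMIs in each of the 3 classes differed by the size step or more in neurons (3.88% elsewhere, and 1.37% of windows held as many). They were Tmem68 (4:3549038 to 3575165), Lyn (4:3678061 to 3813122, ratio 1.44) and Chd7 (4:8690406 to 8868738, ratio 0.754), the last 2 chosen after their values were seen. Car8 (4:8141533 to 8239088, ratio 0.457) was left out with 96 UMIs in satellite glia-like cells. Within 10 Mb 3 of 27 differed (9.46% of windows), so a segment carried along with the floxed allele stays open for these flanking genes in neurons. None of the 48 genes lies within 5 Mb of Penk, and the nearest on chromosome 4 was Cd72 (4:43446431 to 43455129). A segment of that width is thus argued against as the account of the 48 genes. The genotype itself was not tested as a cause, cannot be told apart from other differences between the pools, and stays open.

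The immediate early and glucocorticoid response lists were lower in neurons of the Treg_Penk_KO library, with median log2 ratios of -0.23 and -0.19. Another mix of the named neuron subtypes is argued against, as the medians were -0.25 and -0.20 with subtypes weighted equally, below their random lists. Equal weights leave the mix of clusters within a subtype as it was, so that mix stays open. A process of neurons alone is argued against because the immediate early median was also below the random lists in 4 of 6 other named classes. These were endothelial-like, fibroblast-like, myelinating Schwann-like and satellite glia-like cells. Of the measured members, 25 of 26, 24 of 25, 23 of 28 and 24 of 27 had levels at least as high there as in neurons. The satellite glia-like median turned from -0.16 to 0.035 at Leiden resolution 0.5, which leaves 3 classes. Of these, the myelinating Schwann-like median was too small to be recomputed under the alternatives, so only the endothelial-like and fibroblast-like medians were checked there. Deeper cells in the control library cannot be told apart from a lower level, since in cells thinned to 500 UMIs the medians were -0.13 (random lists -0.15 to 0.14, 20 genes measured) and -0.052 (-0.10 to 0.11), both inside the range of their random lists. RNA of other cells carried into neurons was not tested for these lists and cannot be told apart from a lower level in neurons. Satellite glia markers were 0.275% of neuronal UMIs in the control and 0.234% in the Treg_Penk_KO library. With 1 library per genotype, the genotype cannot be told apart from differences between the pools in handling or sampling time. Neither was tested as a cause, and both stay open.

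A cluster of all cells named Mrgprd nonpeptidergic-like, led by Mrgprd together with the peptide genes Adcyap1, Tac1 and Calca, stood apart because it held 133 Treg_Penk_KO cells (1.1035% of the library, median 4197 UMIs) and 15 control cells (0.0956%, median 3437). Its name needed no lead over other neuron subtypes, so these cells were not set apart from peptidergic C-like neurons. Doublets had been kept, and whether these cells are doublets was not tested. An unnamed cluster led by Fn1, Col1a1 and Col3a1 stood apart because it held 22 Treg_Penk_KO cells (0.183%) and 1 control cell (0.0064%).

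Median ratios of 4 gene lists went in opposite directions among neuron subtypes, and these differences between subtypes were not tested. Of these lists, only the interferon response list was recomputed in subtypes under the alternatives. Extracellular matrix genes were at 0.718 in A-beta LTMR-like and 0.810 in peptidergic A-fibre-like neurons but at 1.29 in Mrgpra3 pruriceptor-like, 1.27 in Mrgprd nonpeptidergic-like and 1.153 in proprioceptor-like neurons. Interferon response genes were at 0.785 in A-delta LTMR-like but at 1.13 in C-LTMR-like and in peptidergic C-like neurons, the latter turning to a log2 ratio of -0.032 with cells thinned to 500 UMIs. Itch receptors and mediators were at 0.593 in A-delta LTMR-like, 0.752 in Trpm8 cold-like and 0.894 in Mrgpra3 pruriceptor-like neurons but at 1.12 in proprioceptor-like neurons. Many members of the itch list served as markers of pruriceptor-like and Mrgprd nonpeptidergic-like neurons. In the other subtypes, RNA of those neurons cannot be told apart from a shift of their own. Satellite glia reactivity genes were at 0.620 in A-beta LTMR-like, 0.697 in A-delta LTMR-like, 0.8195 in Trpm8 cold-like, 0.8215 in peptidergic A-fibre-like, 0.852 in C-LTMR-like and 0.882 in peptidergic C-like neurons but at 1.12 in Mrgprd nonpeptidergic-like neurons. Genes of the matrix and satellite glia lists are largely products of other cells, and 2 of these subtypes drew on their clusters unevenly: a cluster with the glial gene Apoe among its top genes held 336 of 932 control and 89 of 564 Treg_Penk_KO peptidergic A-fibre-like cells, and another held 146 of 1359 and 232 of 1097 Mrgprd nonpeptidergic-like cells.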

How the results depend on the processing

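The alternatives with top-scoring doublets removed, droplets with a cell of 1 library and neurons of named subtypes only were chosen after the data were seen. No paired analysis was possible because each group is 1 library. A split by probe barcode was not run because each library carries 1 probe barcode, and neither was removal of doublets at Scrublet's automatic threshold, which marked 0 cells in 1 library and 44.7% in the other. Of the values recomputed, 18 of 20 for Penk, 56 of 60 for class shares, 60 of 65 for subtype shares, 166 of 207 for lists in neurons, 448 of 619 for lists in other classes and 1033 of 1310 for expression stayed within their counting intervals or limits of size, and 4, 31 and 17 of the last 3 kinds reversed. Scaling by the median ratio and leaving unnamed clusters out of the denominator moved none. Only lists outside their random range were recomputed. In other named classes this was done where the median differed by at least 1.1-fold. In named neuron subtypes it was done for the immediate early, glucocorticoid and interferon lists alone. Lists in unnamed clusters were not recomputed. Where a value below moved or reversed, the cause was not tested. Lists are given as median log2 ratios, shares as ratios and genes as log2 ratios, and depth limits values that rest on few UMIs, whose counting intervals are wide.

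In droplets with a cell of 1 library, share ratios went from 1.11 to 0.937 for endothelial-like, 0.979 to 0.917 for myelinating Schwann-like, 0.851 to 1.09 for A-delta LTMR-like, 1.05 to 0.959 for Mrgprd nonpeptidergic-like and 0.788 to 0.880 for peptidergic A-fibre-like cells. In neurons the itch list was at 0.19, satellite glia reactivity at -0.094, myelin at -0.12 and red blood cell genes at -0.0945. Axon injury in macrophage-like cells reversed to 0.074, and in proprioceptor-like neurons immediate early genes reversed to 0.10 and the glucocorticoid list to 0.0036. With the top-scoring doublets removed, the fibroblast-like share ratio went from 0.999 to 0.906 and the Mrgprd nonpeptidergic-like to 1.154. The itch list reversed in endothelial-like cells (0.082), apoptosis in fibroblast-like cells (-0.056), myelin in myelinating Schwann-like cells (-0.22), interferon in A-beta LTMR-like neurons (-0.045) and Calb2 in satellite glia-like cells (1.96 to -0.86), while in neurons itch was at 0.20, satellite glia reactivity at -0.008 and myelin at -0.037. With at least 1500 UMIs, the fibroblast-like share ratio was 1.24 and red blood cell genes in neurons were at -1.65, while myelin in myelinating Schwann-like cells (-0.14) and interferon in A-beta LTMR-like neurons (-0.055) reversed.

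With cells thinned to 500 UMIs, neuronal lists moved to -0.13 for immediate early, 0.021 for axon injury, 0.042 for neuropeptides, 0.0006 for Gi and cAMP, 0.19 for itch, 0.067 for interferon, -0.017 for satellite glia reactivity, -0.0597 for myelin and -0.052 for glucocorticoid genes. Lists that reversed were apoptosis in fibroblast-like cells (-0.0085), inflammatory cytokines in myelinating Schwann-like (-0.14) and satellite glia-like cells (-0.24), interferon in A-beta LTMR-like (-0.15), Trpm8 cold-like (0.051), peptidergic A-fibre-like (-0.0596) and peptidergic C-like neurons (-0.032), glucocorticoid genes in C-LTMR-like (0.042) and immediate early genes in peptidergic C-like neurons (0.14). Genes that reversed were Cbln1 (-0.025), Calb2 (0.0499), Trpa1 (-0.0696) and Atf3 (0.11) in neurons, Slc1a2 in satellite glia-like cells (-0.078), Rtl8b in peptidergic A-fibre-like (0.0401) and Cidea in proprioceptor-like neurons (-0.20). Penk kept its direction, but its values of -4.37 in neurons and -4.27 in Trpm8 cold-like neurons rest on the UMI added to 0 Treg_Penk_KO UMIs, where the counts show at least 6.66-fold and 6.13-fold lower, against 1 UMI in neurons (-6.68) and at least 51.9-fold lower in Trpm8 cold-like neurons with all UMIs.

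With subtypes weighted equally, axon injury (-0.078), neuropeptides (-0.0021), cholesterol synthesis (-0.0099) and Oprd1 (0.043) reversed, and nociceptive channels were at 0.027, itch at 0.025, interferon at 0.068 and red blood cell genes at -0.32. With the mean over cells, neuronal lists were at 0.065 for neuropeptides, 0.019 for Gi and cAMP, 0.031 for nociceptive channels, 0.10 for itch, 0.061 for interferon, -0.0017 for satellite glia reactivity, 0.0024 for cholesterol synthesis, -0.063 for myelin, -0.031 for circadian and -0.0034 for hypoxia genes. Under that setting itch (-0.11), inflammatory (-0.11) and red blood cell lists (0.44) reversed in satellite glia-like cells, the glucocorticoid list in C-LTMR-like (0.12) and proprioceptor-like neurons (0.007) and interferon in Trpm8 cold-like neurons (0.10), as did Oprk1 (-0.0083), Jun (0.038) and Atf3 (0.011) in neurons, Ramp3 (-0.36) and Syt13 (-0.36) in A-beta LTMR-like and Sstr1 (-0.27) in peptidergic C-like neurons.

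At Leiden resolution 0.5, 1 of 10 neuron subtype shares moved, that of the unnamed neuron cluster. In neurons, neuropeptides were then at 0.13, myelin at -0.12 and red blood cell genes at -0.31, and potassium channels (0.0011) and Atf3 (0.0275) reversed. Cidea in proprioceptor-like neurons (-0.16) also reversed, as did immediate early (0.035), itch (-0.0445) and inflammatory lists (-0.078) in satellite glia-like cells. At resolution 2.0 apoptosis in fibroblast-like cells (-0.0037) and itch in satellite glia-like cells (-0.012) reversed. With members of at least 1 UMI neuropeptides were at 0.12, with no cell filter myelin was at -0.069 and with named subtypes only red blood cell genes were at -0.56, all in neurons. With members of at least 200 UMIs, inflammatory genes in satellite glia-like cells (-0.012) and immediate early genes in Trpm8 cold-like neurons (0.013) reversed. Of neuronal genes with at least 100 UMIs and 20 CPM, 98.8% lay within the size step, and 92.8% did with thinned cells, 98.2% at resolution 0.5, 99.2% with doublets removed, 99.2% with equal weights and 99.6% with the mean over cells.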

Other observations

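The gene groups of cells that fall outside the named classes were chosen for description after their values were seen. The unnamed cells led by Igfbp6, Islr and Thbs4, 588 in the control and 533 in the Treg_Penk_KO library, had 12 of 23 immediate early genes lower and 2 higher (median log2 ratio -0.34), 9 of 22 glucocorticoid-induced genes lower and 0 higher (-0.25) and 9 of 18 clock genes lower and 2 higher (-0.31). Interferon response genes were higher there, with 13 of 34 higher and 3 lower (0.29), and the itch list was at 0.23. A second unnamed cluster, of 447 and 320 cells, had 16 of 25 extracellular matrix genes higher and 2 lower (0.52) and 9 of 19 satellite glia reactivity genes higher and 0 lower (0.26), with nociceptive channel genes at -0.19. In the unnamed cells led by globin genes, 848 and 616 cells, clock genes had 8 of 12 lower and 0 higher (-0.42), and the red blood cell list was at -4.91.

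A small group of neurons in each library carried genes of the axon injury list. It made up 14 of 6620 control neurons (0.211%, 0.116 to 0.355) and 12 of 5085 Treg_Penk_KO neurons (0.236%, 0.122 to 0.412), with median depths of 22444.5 and 29665 UMIs, and 8 of its 12 leading genes belong to that list. In these cells Atf3 was at 966 and 1049 CPM against 19.2 and 16.8 CPM in the other neurons, and Sprr1a at 448 and 1646 CPM against 2.97 and 1.13 CPM. Gap43 was at 3425 and 3271 CPM against 365 and 402 CPM, and Ecel1 at 653 and 475 CPM against 0.742 and 0.706 CPM. Sprr1a, at 3.56 and 5.39 CPM over all neurons, was thus lower, not higher, in the Treg_Penk_KO library outside this group.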
